A study of Danio rerio with 10 samples.

How the data were processed

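Gene expression was measured in sorted zebrafish cells with 10 single-colour NimbleGen expression arrays, 5 from embryos given a caged morpholino against ntla and 5 from control embryos. The gene ntla (no tail a, current symbol tbxta) encodes a T-box transcription factor of the notochord lineage. A morpholino is an antisense oligomer that blocks translation or splicing of its target, and a caged one is inactive until light releases it. Per the labels, zygotes received either the caged morpholino with caged fluorescein dextran or the dextran alone. A region 100 µm across in the posterior chordamesoderm, 125 µm anterior to Kupffer's vesicle, was irradiated at 12 hours post fertilisation (hpf) with light of 360 nm. At 16 hpf the cells made green by the light were isolated by flow sorting, with 30 embryos and about 8000 cells behind each sample. RNA was reverse transcribed and amplified as whole-transcriptome cDNA in 22 PCR cycles.

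Per the file headers, the raw probe values are scanner intensity values read with NimbleScan 2.4.67. Per the labels, the array provider then made gene-level intensity values for the authors by robust multi-array averaging (RMA), with background correction and normalisation, and these are deposited on a linear scale. The deposited per-gene files also hold a score for the error of each gene value, which was not used. The deposited table of 18 gene sequences holds the same RMA values for those sequences, and the rule by which they were chosen is not given in the sources used here. The study called genes with a moderated test at a fold change over 2 and a p under 0.1, per the labels.

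Values for the results were made from the raw intensities. Background was corrected with normexp at an offset of 50 on all spots, the random-sequence control probes were left out, and the 385000 gene probes were quantile normalised between arrays. The log2 probe values were summarised for each of 37157 gene sequences by median polish. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with group as the only term), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Single genes were also compared by a two-sided exact permutation test of the 10 array values, whose smallest possible p is 0.00794.

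A gene sequence was taken as above background on an array when its median raw intensity exceeded the 95th percentile of the random-sequence probes there. Signal over background, the median raw gene probe over the median random probe, ran from 1.68 to 5.46, and 37.1% to 80% of gene sequences were above background per array. The shares were 42.3, 80.0, 70.4, 72.1 and 64.8% for caged morpholino replicates 1 to 5. For control replicates 1 to 5 they were 64.7, 78.7, 52.2, 37.1 and 41.6%. A gene's counts of arrays above background can therefore differ between groups through the arrays alone. The number of arrays limits the precision. The dates in the headers put the arrays in 3 groups, taken here as scan batches. Batch 1 holds replicate 2 of both groups, batch 3 holds control replicate 1, and batch 2 holds the other 7 arrays.

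The files give no current symbol for many sequences. Names were taken from the symbols, markers and homologues in the files. Where a match was found, they were brought up to date through the gene table given for assembly GRCz12tu, which served only for names. This named 21926 of the 37157 gene sequences, with 14920 distinct names, and 3974 sequences kept a transcript symbol as the files give it. Names from transcript symbols were not checked against the chromosome. Positions are Zv7 coordinates as the files give them.

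A total of 16 gene lists with 347 entries was fixed before the data were examined, and 299 entries were measured, each by the sequence with the highest mean over all arrays. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 16 lists, with an estimated correlation and with fry beside it. Each list's median was also set against 10000 random lists matched on mean signal. The genes named are ntla, the 5 genes with the smallest p in each direction among sequences with exactly 1 gene symbol, 1 sequence per symbol (the rule for fewer than 5 passing genes), and up to 4 members of each list with the smallest p. The result of 1 of the 16 lists is not reported here. Any other sequence named is said to be chosen after its values were seen.

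The tests were checked on simulated data of 37157 gene sequences in 5 against 5 arrays. With 200 changed sequences and the residuals of the real arrays, 54.5% of 2-fold and 97.6% of 4-fold changes were recovered. With 20 changed sequences the shares were 18% and 90.5%. The set test was checked on random lists in independent noise, not on the residuals of the real arrays. It called 20 of 20 lists shifted by 1 log2 unit and 0 of 300 unshifted lists. That check lacks the correlation between members of the real lists, and its shift is larger than theirs. It therefore gives neither the rate of false calls on these arrays nor the power for small shifts.

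Alternatives covered the replicate number as a block, the authors' deposited values, background correction, normalisation, probe summary, a filter on dim sequences, array weights, the empirical Bayes settings and leaving out each array. The list tests used the array weights, the variance trend or the correlation within a random replicate block of the setting they belong to, but not its robust part, which camera lacks. Terms for scan batch and for principal components of the within-group residuals were added after seeing the data. A measure of 3′ against 5′ probe signal along each transcript was revised after its first values were seen, because log2 raw intensity carries the background level of the array, and both versions are reported in the closing section.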

Results

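The data cover 10 arrays of light-marked posterior chordamesoderm cells, the precursors of the notochord, sorted at 16 hpf from zebrafish embryos. A total of 5 arrays came from embryos in which an ntla caged morpholino (cMO) was released at 12 hpf, and 5 from irradiated embryos given only the caged dye. The labels call the 5 samples of a group biological replicates. Median raw gene probe signal was 1.68 to 5.46 times that of random-sequence probes. The comparison asks which transcripts differ in these cells once the ntla morpholino is released. The controls held no morpholino, so dependence on ntla cannot be told apart from a general effect of a morpholino or its release.

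The targeted gene was measured first. The ntla transcript, read by 12 probes of a sequence at Zv7 chromosome 19, 20033640 to 20038792, was higher in the cMO arrays than in controls. Its log2 intensity was 13.93 ± 0.42 (SD, n = 5) against 12.81 ± 0.46 (n = 5), a 2.19-fold difference. The cMO arrays read 13.65, 13.86, 13.46, 14.54 and 14.15 for replicates 1 to 5, and the control arrays 12.3, 12.81, 12.48, 13.47 and 12.96. The log2 difference of 1.13 (SE 0.245, 95% interval 0.60 to 1.65) had an exact permutation p of 0.0159 by itself. It did not pass the adjustment over all gene sequences (limma adjusted p = 1). A morpholino need not lower the level of its target transcript, so the direction does not check the labels. The difference was 1.05 between the lone cMO and control arrays of scan batch 1, 0.98 within scan batch 2, and 1.00 with scan batch as a term.

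No gene sequence passed the adjusted threshold. Of 37157 gene sequences, limma called 0 higher and 0 lower at an adjusted p of 0.05, and 0 at 0.1. An unadjusted p under 0.05 was reached by 339 sequences, 201 higher and 138 lower in the cMO arrays, where 1858 are expected if none differed. Neither the number nor the balance was stable. With 1 and 2 principal components of the within-group residuals as terms the number was 1212 and 1837. Those terms leave each difference unchanged and take out residual spread, so these 2 counts do not speak to stability. The number was 1781 with array weights and 190 to 763 with an array left out. Within scan batch 2 it was 159 higher and 261 lower, with scan batch as a term 245 and 303, with the replicate block 231 and 249, and without cMO replicate 4 342 and 421. The values of the 2 groups did not overlap for 91 sequences, against 295 that chance gives (0.794% of sequences) and a median of 123 over other splits of the arrays.

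**Figure D1:**
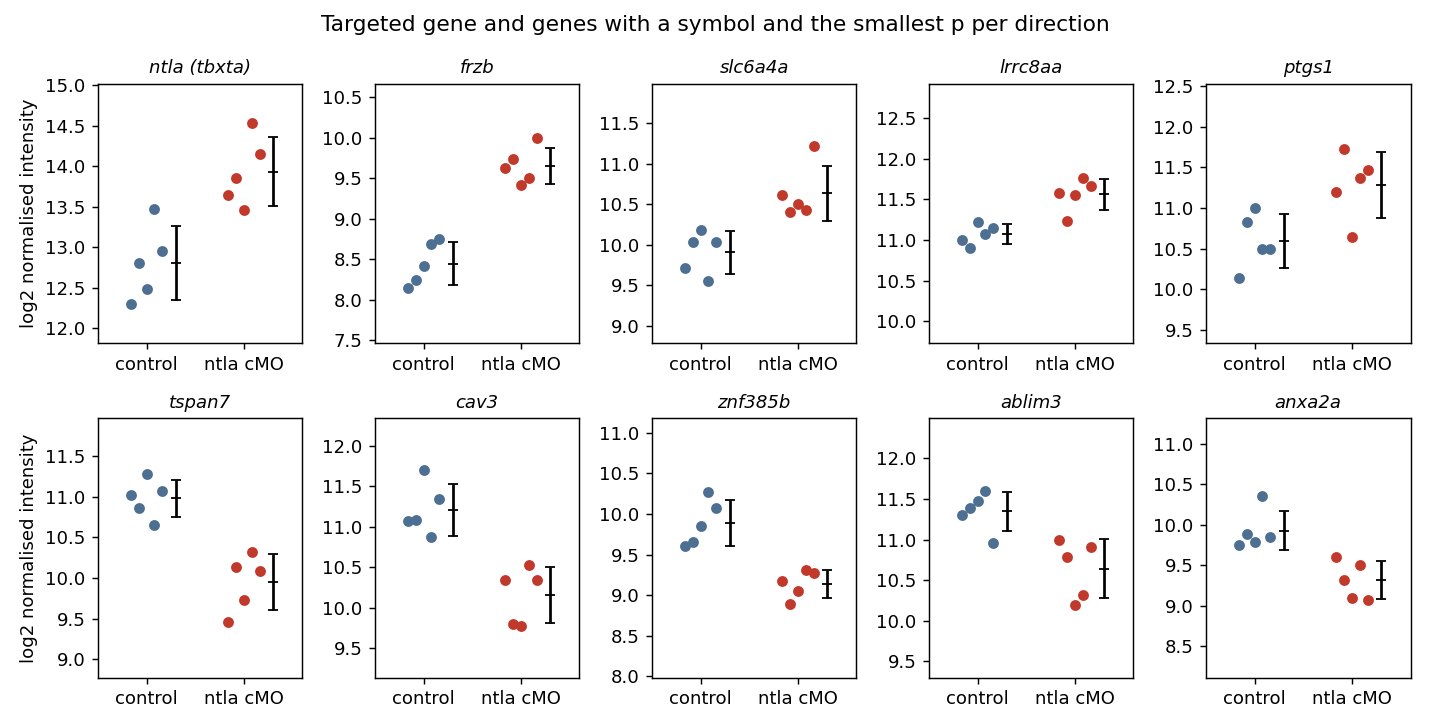
Log2 normalised intensity of ntla and of the other genes with a symbol that had the smallest p in each direction, one panel per gene with a vertical axis of equal length, 5 control and 5 ntla cMO arrays as points and mean ± SD beside them. The ntla arrays averaged 13.93 with the morpholino and 12.81 without, and none of these genes passed the adjusted threshold.

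Among sequences with a gene symbol, those with the smallest p in the higher direction, none of which passed, were frzb, ntla, slc6a4a, lrrc8aa and ptgs1. The sequence of frzb, which encodes a secreted antagonist of Wnt signalling, lies at chromosome 9, 38641698 to 38647554. Its log2 intensity was 9.65 ± 0.22 (SD, n = 5) against 8.44 ± 0.27 (n = 5), a 2.32-fold difference with no overlap between groups (exact permutation p = 0.00794). Its adjusted p was 0.2, and 1 of the 5 control arrays read it above background. Over the alternative settings its log2 difference ran from 0.855 to 1.732, the latter in the authors' deposited values, and the filter on dim sequences removed it. Its adjusted p went no lower than 0.056, with 2 principal components as terms. The serotonin transporter gene slc6a4a differed by 0.73 ± 0.189 (SE) on the log2 scale. The difference was 0.69 ± 0.217 (SE) for ptgs1, which encodes a cyclooxygenase, and 0.49 ± 0.147 (SE) for lrrc8aa, a volume-regulated anion channel subunit.

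In the lower direction the smallest p among sequences with a gene symbol belonged to tspan7, cav3, znf385b, ablim3 and anxa2a, and again none passed. The muscle caveolin gene cav3 (chromosome 6, 22344742 to 22352456) read 10.16 ± 0.35 (SD, n = 5) in the cMO arrays and 11.21 ± 0.32 (n = 5) in controls, a log2 difference of -1.05 with an exact permutation p of 0.00794. Its other sequence differed by -1.03, but was above background on only 2 of 5 cMO arrays, against 5 of 5 control arrays. The tetraspanin gene tspan7 read 9.95 ± 0.35 against 10.98 ± 0.23, and its 3 sequences differed by -1.03 to -0.69. All 7 sequences named znf385b, a zinc finger gene, were lower, by -1.01 to -0.52. For ablim3, which encodes an actin-binding protein, the log2 difference was -0.70 ± 0.191 (SE), but the 10 sequences carrying that name disagreed and ran from -0.70 to 0.04. The annexin gene anxa2a differed by -0.61 ± 0.169 (SE). Between the lone arrays of scan batch 1, within scan batch 2 and with scan batch as a term, the log2 differences were 1.496, 1.02 and 1.13 for frzb. They were -1.28, -1.05 and -1.10 for cav3, and -0.73, -1.10 and -1.02 for tspan7.

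By the study's own threshold, a fold over 2 with an unadjusted p under 0.1, the authors' deposited values gave 19 gene sequences, 4 higher and 15 lower in the cMO arrays. After Benjamini-Hochberg adjustment of that p, 0 remained. Values made from the raw intensities gave 10 sequences, 2 higher and 8 lower, but 3 (1 higher, 2 lower) with no background correction, and 4 higher against 3 lower without cMO replicate 3. The authors' deposited table lists 18 sequences, 3 higher and 15 lower here, and 17 of them were among the 19. It was chosen on these same samples, so it is not independent evidence of direction. It holds ntla, frzb, tspan7, 2 sequences of cav3 and 4 of znf385b. In the authors' deposited values the count was 62 without control replicate 2 and 43 without cMO replicate 1. It was 39 there without cMO replicate 4 and 34 without cMO replicate 2. In the same values it was 29 with scan batch as a term and 65 within scan batch 2.

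The notochord list did not shift as a group. Of its 20 measured members 10 were higher and 10 lower, with a median log2 difference of -0.01 and a mean of 0.03 (camera adjusted p = 0.961). None passed over all genes, and only ntla itself, the target of the morpholino, passed when adjusted over the list alone. Without ntla the mean of the other 19 was -0.026. The next members with the smallest p were the hedgehog ligand gene ihhb at -0.48 ± 0.153 (SE), the proteoglycan gene epyc at -0.31 ± 0.159 and shhb at 0.30 ± 0.165. The epyc value says little, since only 1 of 5 cMO and 1 of 5 control arrays read it above background, and ihhb was above it on 3 of 5 in each group. Among 28 muscle differentiation genes 19 were lower and 9 higher, with a median of -0.04 (adjusted p = 0.0681). Over all genes 0 passed, and adjusted over the list alone only cav3 did, without which the mean went from -0.061 to -0.024. It was followed by the slow myosin gene smyhc1 at -0.42 ± 0.164 (SE) and the myosin chaperone gene unc45b at 0.35 ± 0.171. The muscle list passed in 9 of 26 alternative settings at the preset correlation, with adjusted p from 0.00782 to 0.485, but over all arrays its adjusted p was 0.743 with an estimated correlation. Its mean turned positive without control replicate 3 (range -0.133 to 0.039 when each array was left out). In scan batch 1, in scan batch 2 and with scan batch as a term, the mean was 0.02, -0.12 and -0.09 for muscle and -0.11, 0.00 and -0.02 for notochord.

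A total of 6 lists passed camera at the preset correlation, all higher in the cMO arrays, and no member of any passed singly, over all genes or adjusted over the list alone. None of the 6 calls held with an estimated correlation, where the adjusted p was 0.659 for the secretory pathway and 0.378 for each of the other 5, and fry called 0 lists. Of the secretory pathway genes 31 of 35 were higher (median 0.13, adjusted p = 0.00034), among them the endoplasmic reticulum chaperone genes hspa5 at 0.44 ± 0.236 (SE) and hsp90b1 at 0.39 ± 0.185. Epidermis and enveloping layer genes were higher for 16 of 19 (median 0.18, adjusted p = 0.000971), with tp63 at 0.46 ± 0.221. Endothelium and blood genes were higher for 15 of 17 (median 0.24, adjusted p = 0.00142), with the myeloid factor gene spi1b at 0.34 ± 0.147. Its leading members were dim: spi1b was above background on 5 of 5 cMO and 3 of 5 control arrays, cdh5 on 4 and 2. The list mean was 0.118 with no background correction and 0.226 in the authors' deposited values (camera adjusted p = 0.00277 and 0.0008 at the preset correlation). Neural genes were higher for 21 of 26 (median 0.12, adjusted p = 0.00322), with hoxb1b at 0.44 ± 0.234. Stress and immediate early genes were higher for 12 of 15 (median 0.14, adjusted p = 0.00366), with dusp5 at 0.45 ± 0.198 and egr1 at 0.39 ± 0.184. Floor plate genes were higher for 9 of 13 (median 0.18, adjusted p = 0.0165), with foxa2 at 0.31 ± 0.178. The floor plate entries foxa2, foxa, shha, shhb and ctgfa also stand in the notochord list, so those lists are not independent.

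Within scan batch 2 camera called only the secretory pathway and stress of these 6 lists, and muscle differentiation, which was lower (adjusted p = 0.00782). The adjusted p there was 0.297 for the floor plate, 0.377 for neural genes and 0.279 each for endothelium and epidermis. The secretory pathway mean was 0.23 in scan batch 2 against -0.13 between the lone cMO and control arrays of batch 1. With scan batch as a term it was 0.15. The means in batch 1, in batch 2 and with the batch term were 0.31, 0.10 and 0.15 for epidermis. They were 0.54, 0.12 and 0.21 for endothelium and blood, and 0.24, 0.08 and 0.12 for neural genes. For stress they were 0.05, 0.19 and 0.16, and for the floor plate 0.06, 0.10 and 0.09. With scan batch as a term the floor plate call was lost (adjusted p = 0.223), while the others of the 6 held. Leaving out scan batch 1 lost the neural call (adjusted p = 0.135) and the endothelium and blood call (adjusted p = 0.385). The count of called lists was 1 without cMO replicate 1 and 2 without cMO replicate 5. Single arrays moved the means as well. The secretory pathway mean of 0.15 was 0.04 without control replicate 4 (adjusted p = 0.447) and 0.31 with array weights. The endothelium and blood mean of 0.16 was 0.075 without control replicate 2 (adjusted p = 0.302), and the epidermis mean of 0.17 was 0.09 without cMO replicate 2 (adjusted p = 0.199) and 0.29 with array weights. Without cMO replicate 5 the floor plate mean went from 0.12 to 0.058 (adjusted p = 0.301), the neural mean from 0.12 to 0.058 (adjusted p = 0.301) and the stress mean from 0.14 to 0.07 (adjusted p = 0.262). With array weights the stress mean was 0.21.

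**Figure D2:**
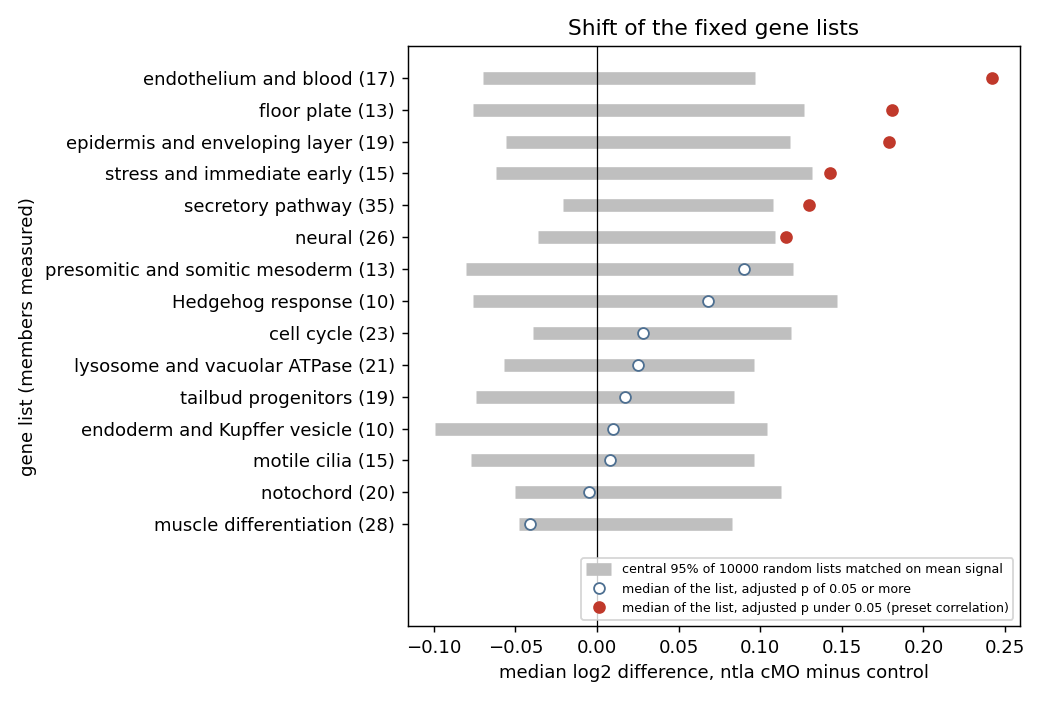
Median log2 difference (ntla cMO minus control) of the members of each fixed list reported here, with the number of members measured, as points, and the central 95% of 10000 random lists matched on mean signal as bars. Filled points mark the 6 lists past the preset-correlation test, from 0.12 for neural to 0.24 for endothelium and blood, none of which passed with an estimated correlation.

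The other lists reported here did not pass. Presomitic and somitic mesoderm had a median of 0.09 (adjusted p = 0.19, 8 of 13 higher), with dlc at 0.32 ± 0.146 (SE). Tailbud progenitors had a median of 0.02 (adjusted p = 0.339, 10 of 19 higher), with sp5l at 0.47 ± 0.189, and passed at the preset correlation once the dimmer sequences were left out (adjusted p = 0.0279). Over all sequences the adjusted p with an estimated correlation was 0.667. Hedgehog response had a median of 0.07 (adjusted p = 0.657, 7 of 10 higher), with olig2, above background on 4 of 5 cMO and 1 of 5 control arrays, at 0.28 ± 0.159. Endoderm and Kupffer vesicle stood at 0.01 (adjusted p = 0.535), with foxa1 at 0.37 ± 0.207, and motile cilia at 0.01 (adjusted p = 0.657), with foxj1a at 0.29 ± 0.204. Cell cycle stood at 0.03 (adjusted p = 0.572, and 0.926 with an estimated correlation), with rrm1 at 0.23 ± 0.184. Its mean of 0.05 was 0.22 with array weights (adjusted p = 0.00157 at the preset correlation). It was 0.19 without cMO replicate 4 (adjusted p = 0.00516), 0.15 without control replicate 2 (adjusted p = 0.0302) and 0.16 without control replicate 3 (adjusted p = 0.0128), but -0.09 without control replicate 4 (adjusted p = 0.0519). Lysosome and vacuolar ATPase had a median of 0.03 and a mean of 0.02, while camera's direction, relative to other genes, was down (adjusted p = 0.966). Its members with the smallest p were rab32a at -0.25 ± 0.151 (SE), ctsd at 0.31 ± 0.185 and lamp1a at -0.22 ± 0.154.

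The arrays did not separate by group. The first principal component held 48.9% of the variance, with mean positions of -4.4 ± 47.8 (SD, n = 5) for cMO and 4.4 ± 52 (n = 5) for control arrays (exact permutation p = 0.81). Pairs of arrays correlated across gene sequences, which are not independent replicates, at a median of 0.949 within groups and 0.954 between groups.

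**Figure D3:**
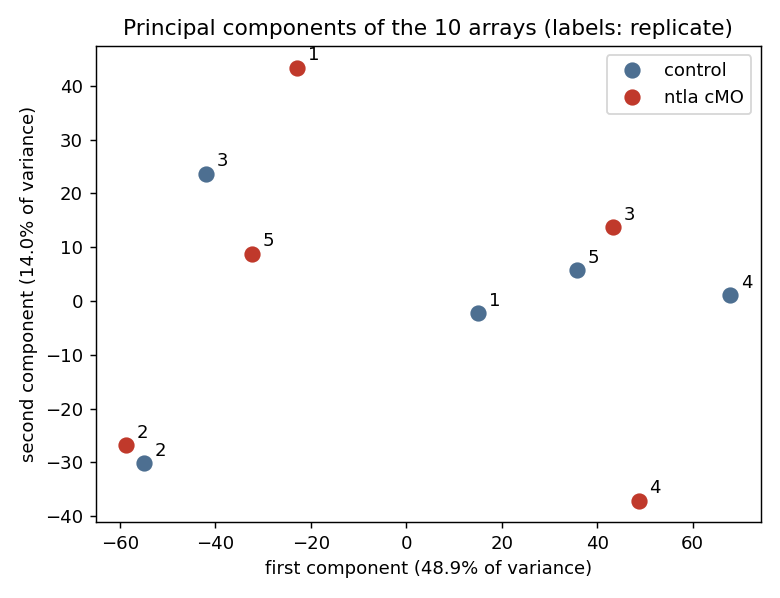
Position of the 10 arrays on the first and second principal components of the log2 values (48.9% and 14% of the variance), labelled by replicate number and coloured by group. Both groups spread over the first axis, and replicate 2 of both groups, which form scan batch 1, lie together.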

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

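The tests of scan batch and tailbud cells for ntla, and those of signal over background, transcript coverage and the morpholino for the main axis, were set after related values had been seen. In 150 groups of 5 arrays tested for a single array far from the rest, 9 were found, and chance alone flags about 1 in 20.

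The ntla signal was higher in the arrays with the ntla morpholino, by 1.13 on the log2 scale. A few odd probes do not account for it, since 91.7% of its 12 probes were higher in the cMO arrays. Scan batch does not either, since 86.9% of the difference was present within scan batch 2. More tailbud cells in the sort were predicted to raise the other tailbud genes about as much. The median of the 19 measured members was 0.02 with an SD of 0.18. Dim members can show little, such as wnt8b, above background on 2 of 5 cMO and 1 of 5 control arrays. With the dimmer sequences left out the list mean was 0.14 (camera adjusted p = 0.0279 at the preset correlation). Both values lie below the ntla difference, but a smaller excess of tailbud cells is not excluded. An effect of the morpholino stays open, with no test beyond the group difference itself, and ntla did not pass the adjusted threshold.

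For the 6 lists that passed at the preset correlation, 6 of 6 medians lay outside the central 95% of matched random lists. Expression level alone therefore did not give medians of that size. It can carry part of them, since the matched medians ran from 0.013 for endothelium and blood to 0.046 for the secretory pathway. The random lists lack the correlation between members of the real lists, so this comparison does not speak to chance. Chance cannot be excluded: 35 of 100 splits of the arrays (of 126 possible) called at least 6 lists, and the highest other split called 10. No biological explanation is therefore put forward for them.

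The arrays differ along 1 main axis. The morpholino does not define it, with both groups spread along it and an exact permutation p of 0.81. Signal over background correlated with it at r = -0.66 (permutation p = 0.0239, adjusted 0.0319; rho = -0.54, p = 0.115; 10 arrays), but r was -0.28 without the 2 farthest arrays, the pair of scan batch 1, so the relation rests on those. The coverage measure gave r = -0.7 in its first version (permutation p = 0.0194, adjusted 0.0319; rho = -0.68, p = 0.035), -0.44 without the 2 farthest arrays, and r = -0.1 as revised (p = 0.782, adjusted 0.782; rho = -0.08, p = 0.84). For the revised version the 2 farthest arrays were control replicate 1 and cMO replicate 3, and r was 0 without these. The versions differ in background subtraction and in the transcripts used (17642 and 3738), and the first also correlated with signal over background (r = 0.84, p = 0.00819, adjusted 0.0319; rho = 0.67, p = 0.039; 4 relations computed). That r was 0.33 (permutation p = 0.408) without the pair of scan batch 1, so this relation rests on them too. Neither cause could be excluded, and coverage and background cannot be told apart with 10 arrays.

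Of the single arrays far from the rest of their group, cMO replicate 5 read slc6a4a at 11.2 (others 10.4 to 10.6), epyc, near background, at 8.04 (others 8.37 to 8.46) and dlc at 10.6 (others 10.2 to 10.3). Control replicate 4 read anxa2a at 10.4 (others 9.75 to 9.88) and atp6v1ab at 10.2 (others 10.8 to 11.1). The cMO replicate 2 array read her1 at 9.63 (others 10.2 to 10.3), cMO replicate 3 read cdh5 at 9.03 (others 9.45 to 9.58), and control replicate 3 read mdm2 at 11.7 (others 11 to 11.2). Signal over background was 5.46 in control replicate 2 against 1.91 to 2.79 in the other controls.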

How the results depend on the processing

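The scan batch and principal component settings were chosen after seeing the data. No sequence passed an adjusted p of 0.05 under any of the 26 alternative fits, and the 71 named genes gave 0 calls in 1833 gene and setting combinations. At 0.1, 1 sequence passed with the replicate number as a random block (smallest adjusted p 0.0665). With 1 and with 2 principal components 1 sequence passed at 0.1, frzb, at 0.059 and 0.056. The study's threshold applied to the values made here gave 10. The ntla difference stayed between 0.98 and 1.30 with adjusted p from 0.144 to 1. Only ccne1 (-0.02 to 0.201) and mcm7 (-0.075 to 0.443) turned when an array was left out. Counts past the study's threshold in the authors' deposited values ran from 17 to 62 when each array was left out. They were 29 with scan batch as a term, 35 without scan batch 1 and 65 within scan batch 2. From the raw intensities they were 10, 3 with no background correction, 7 to 15 with an array left out, and 21 within scan batch 2. Called lists ran from 1 to 8 when each array was left out, with 3 in scan batch 2 and 0 both with an estimated correlation and by fry. The cause was not tested, except that leaving out arrays leaves fewer samples.

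Mean shifts of lists that were not called changed sign in places, and the cause was not tested. With an array left out they ran from -0.031 to 0.08 for notochord, -0.078 to 0.038 for Hedgehog response, -0.133 to 0.039 for muscle differentiation, -0.034 to 0.116 for endoderm and Kupffer vesicle, -0.016 to 0.056 for motile cilia, -0.067 to 0.083 for lysosome and vacuolar ATPase, and -0.092 to 0.193 for cell cycle. Hedgehog response was -0.015 with cyclic loess, -0.003 with the mean of probes, -0.028 in the upper part of sequences by mean, -0.01 with scan batch as a term, -0.013 without scan batch 1 and -0.033 in scan batch 2. Endoderm and Kupffer vesicle was -0.033 with array weights, and notochord -0.023 with scan batch as a term.

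The design text speaks of paired controls without saying that the replicate numbers mark the pairs. The numbers were not taken as pairs, since deviations of same-numbered arrays did not correlate throughout, at -0.13, 0.77, -0.47, 0.61 and -0.26. These values do not rule pairing out. A total of 4 of 10 arrays correlated best with their own number, and the consensus correlation within a replicate number was 0.163. The replicate block left 0 genes and 6 lists called. For ntla the unadjusted limma p was 6.91e-06 with the block and 0.000411 without, and the adjusted p with the block was 0.144. Sequences past the study's threshold under the block were 10 in the values made here and 21 in the authors' deposited values. Signal over background under 3 on 8 arrays limits what dim sequences can show.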

Other observations

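Sequences chosen here after their values were seen include those with larger differences than the named genes. The unnamed sequence BQ132767 differed by -1.94 ± 0.413 (SE, exact permutation p = 0.00794), and ENSDART00000076345 (chromosome 7, 34413880 to 34421799) by -1.56 ± 0.274 (exact permutation p = 0.00794). Both are in the authors' deposited table. The proteasome subunit gene psmd8, also there, differed by -0.93 ± 0.282 (exact permutation p = 0.0159).

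The counts by the study's threshold and by lack of overlap were set against other splits of the arrays. Of 100 splits, 75 gave at least the 19 sequences of the real split by the study's threshold, and the highest other split gave 2275. Of the same splits 66 gave at least 91 sequences without overlap, and the highest other gave 7928. Chance cannot be excluded for either count. Splits with counts many times the real one point to a structure of the arrays that the groups do not follow.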
